A study of Mus musculus with 4 samples.

How the data were processed

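RNA was sequenced from CD4 T cells sorted from the spleens of Rag-deficient mice, which lack T and B cells of their own. The mice had received naive CD4 T cells 8 weeks earlier and had developed colitis. The donor cells carried either loxP-flanked Esr1 alleles alone (control, 2 libraries) or the same alleles with a Cre recombinase driven from Cd4, which deletes the flanked part of Esr1 in T cells (labelled ERα-deficient, 2 libraries). The labels do not say whether the libraries of a group came from separate mice, so the spread between them may be technical, and p-values measure only the spread between these libraries. Library numbers are shared between the groups, but nothing in the labels ties equal numbers to a shared animal, litter or day, and the libraries were not treated as pairs.

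The values are FPKM, fragments scaled to transcript length in kilobases and to the mapped fragments of the library, computed by the authors and deposited as one table of 16230 genes. HISAT, Bowtie2 and RSEM and the genome build mm10 are named in the submitters' processing notes, without versions or settings. Strand use in the counting is not given in the sources used here, so fragments of a gene and of an overlapping gene on the opposite strand cannot be told apart. RSEM assigns fragments shared by similar transcripts by estimate. A value of exactly 0 can then be a failed assignment: Cox7c, which encodes a subunit of cytochrome c oxidase, was listed at 0 in control 1 while its processed pseudogene copy Gm10012 stood among the highest values. Such values are therefore written as listed at 0. Of the genes, 489 were listed at 0 in all 4 libraries and 5288 in at least 1. The table's NCBI gene identifiers matched the GRCm38.p6 annotation for 16183 genes and did not match for 47. That assembly carries the mm10 coordinates, and gene positions are given from it. 23 symbols that a spreadsheet had turned into dates were restored from the identifiers.

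The table holds no fragment counts, but the depth could be estimated, and fragments recovered for genes with 1 transcript were used for voom weights. For genes with 1 transcript of more than 800 bases (10348 genes), FPKM multiplied by transcript length falls on multiples of what 1 fragment is worth. The step that best fitted low values gave 707000 and 674000 fragments for controls 1 and 2, and 509000 and 565000 for the libraries labelled ERα-deficient 1 and 2. At these steps 79.0% to 80.8% of values lay within 0.2 of a whole fragment, against 50.2% to 52.7% with steps displaced at random. 1 fragment on a transcript of 2000 bases was worth 0.72, 0.76, 1.0 and 0.90 FPKM in these libraries, so values of a few FPKM rest on a few fragments, and 3 fragments, the upper limit of the count that a count of 0 allows, correspond to 2.16 to 3.0 FPKM. These limits cover counting error only.

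Genes with a mean FPKM of at least 1 over the 4 libraries (12896 genes) were tested with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with group as the only term, an empirical Bayes trend on mean expression, two-sided tests and Benjamini-Hochberg adjustment. Genes with an adjusted p under 0.05 were called. Fold changes are the libraries labelled ERα-deficient minus control on the log2(FPKM + 1) scale, which understates the change of low genes. The 4 libraries allow no smaller two-sided exact permutation p than 0.33 for a single gene, so no such test is given per gene. For gene lists, limma's camera was used with its preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists with at least 3 tested genes, with fry beside it. 29 lists were fixed before the data were examined, covering helper T cell types, T cell activation and signalling, proliferation, metabolism, stress, estrogen response, and markers of other cells that a spleen sort could hold. Members called are counted over all genes and adjusted over the list alone. The mitochondrially encoded list had no gene in the table, and the lists of CD8 and gamma-delta T cells, stroma and endothelium, and sex of the cells had 2 tested genes each and no list test at this filter. With no filter their camera adjusted p was 0.286, 0.993 and 0.86.

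The genes named in the text were chosen by a rule also fixed before the data were examined. It took Esr1, Tbx21, Ifng, Il17a, Gata3, Foxp3, Il10, Bcl6 and Mki67 whatever their result. It took in each direction the 10 largest changes among called genes without overlap between the groups' libraries, filled up to 10 by the smallest unadjusted p. It took up to 4 called members of each list, or else the 2 with the smallest unadjusted p. Short RNAs, predicted genes and the list on sex of the cells were left out of the second part. Other genes named beside these were chosen after their values were seen. Il17a was not analysed here, and 1 gene that the rule took is left out of the text, though it stays in the tests of its list and of all genes.

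The procedure was tested on simulated data, with fragments drawn for the real genes at the estimated depths and an assumed dispersion of 0.05, which was not estimated from these libraries, and 200 genes changed, in 5 runs per fold size over about 8569 tested genes. It recovered 11.3% of 4-fold, 68.0% of 8-fold and 81.6% of 16-fold changes, and called on average 7, 10 and 9.6 unchanged genes. In the 4-fold runs all of these unchanged genes, and in the others 9.6 and 8.6 of them on average, were listed at 0 in both libraries of a group. With voom precision weights on the fragments, over about 6581 genes, 67.9%, 80.8% and 87.9% were recovered, with 6.8, 5.2 and 7.2 unchanged genes called. A simulated list of changed genes had a camera p under 0.05 in all 5 runs at each fold size and a list of unchanged genes in 0. The simulated genes were drawn independently, so these runs do not test camera on lists whose genes vary together. In the real lists the estimated correlation was 0.24 for TCR signalling, 0.9 for macrophages and monocytes and -0.02 for follicular helper genes. Camera with an estimated correlation also rests on the few residual degrees of freedom of the libraries. Few lists can therefore pass it, even at a low correlation.

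Alternatives fixed in advance were a pseudocount of 0.1, no filter or a mean FPKM of at least 5, quantile and median-ratio scaling, other empirical Bayes settings, other thresholds, a replicate block and leaving out each library. Added after the data were seen were voom weights on fragments recovered from the FPKM steps for genes with 1 transcript, the removal of short RNAs, and scaling to 23 genes restricted to T cells. That list, a list of 9 genes restricted to regulatory T cells among T cells and a list of 12 red pulp macrophage genes were also written after the data were seen. Tests that need whole fragment counts were planned in case these could be had and were not run. Exon overlaps and shared sequence were taken from GENCODE vM21 on GRCm38, with BLAST+ 2.17.0 at an identity of at least 95% over at least 60 bases, searching with the longest transcript of each gene only. Permutation tests used scipy 1.17.1, and figures matplotlib 3.10.9, under Python 3.11.15.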

Results

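Transcript levels were measured in cells sorted for CD3 and CD4 from the spleens of Rag-deficient mice with transfer colitis, 8 weeks after the mice received naive CD4 T cells. In this model, naive T cells placed in a lymphocyte-free host expand and drive inflammation of the colon. The donor cells were either controls with loxP-flanked Esr1 alleles (2 libraries) or cells in which Cd4-driven Cre was meant to remove estrogen receptor α, the product of Esr1 (2 libraries). The question posed by the design was which transcripts differ when T cells lack this receptor. Depth was low, at an estimated 707000 and 674000 fragments in controls 1 and 2 and 509000 and 565000 in the libraries labelled ERα-deficient 1 and 2. Summed FPKM lay between 444640 and 450656 per library, and 12851 to 13799 genes were above 0. On log2(FPKM + 1) across genes, which are not independent replicates, Pearson's r was 0.902 between the controls and 0.885 between the libraries labelled ERα-deficient. Between groups it ranged from 0.799 to 0.87.

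Esr1 itself had a mean of 0.98 FPKM in the libraries labelled ERα-deficient and 0.12 in controls, and its highest value was in a library labelled ERα-deficient. Esr1 (NCBI gene 13982; GRCm38 chromosome 10, 4611989 to 5005633) had 0.23 FPKM in control 1, was listed at 0 in control 2 and in the first library labelled ERα-deficient, and had 1.96 FPKM in the second. Its mean was under 1 FPKM, so it was not tested. On its longest annotated transcript (6339 bases) these values correspond to about 1.02 and 6.98 fragments, where 3 fragments, the limit that a count of 0 allows, would be 0.67 to 0.93 FPKM. The gene has 5 annotated transcripts, and a gene-level value does not separate the deleted part from the rest of the transcript. The level of Esr1 therefore does not check the labels, and the second group is called the libraries labelled ERα-deficient throughout. Esr2, which encodes estrogen receptor β, had 94.4 ± 38.4 FPKM (SD, n = 2) in controls and 125 ± 55.5 (SD, n = 2) in the libraries labelled ERα-deficient, with a log2 fold change of 0.39 ± 0.45 (SE) and an adjusted p of 0.707 in limma. Exon overlap and shared sequence were not examined for Esr2. Several genes not typical of T cells had high values in all libraries, so this level does not show that the receptor is abundant.

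The clearest contrast between the groups was a low level of T cell transcripts together with a high level of myeloid transcripts in the libraries labelled ERα-deficient. Cd3g, a chain of the T cell receptor complex (NCBI gene 12502; chromosome 9, 44969572 to 44980431), had 194 ± 10 FPKM (SD, n = 2) in controls and 26.3 ± 0.66 (SD, n = 2) in these libraries. Hmox1, the heme oxygenase of red-cell-clearing macrophages (NCBI gene 15368; chromosome 8, 75093618 to 75100593), had 24.8 ± 23.8 FPKM (SD, n = 2) and 426 ± 38.3 (SD, n = 2). Neither passed on its own, with log2 fold changes of -2.84 ± 0.27 (SE, adjusted p = 0.079) and 4.45 ± 0.72 (SE, adjusted p = 0.12) in limma, but in both genes the libraries of the groups did not overlap. The log2 fold change of Hmox1 was 3.32 without control 1 and 5.58 without control 2. Of 12896 genes tested, 2 rose and 5 fell at an adjusted p under 0.05, while 1173 had higher and 877 lower values at an unadjusted p under 0.05. Non-overlapping values in the higher direction were found for 23.2% of tested genes and in the lower direction for 25.7%, where chance gives 16.7% in each. With voom weights on the recovered fragments, chosen after the data were seen, 138 genes rose and 49 fell of 6571 tested in limma. Hmox1 was among those that rose (adjusted p = 0.00646) and Cd3g among those that fell (0.00968). Scaling the libraries to genes restricted to T cells, also chosen afterwards, gave 9133 higher and 34 lower genes and moved the median log2 fold change of all tested genes from -0.07 to 2.11. It divides all values of a library by the same factor, so the order of the lists hardly changes. A list below the median of all genes on this scale is therefore no separate evidence. A median above 0 there means that a lower list fell less than the genes restricted to T cells.

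All 7 genes past the threshold were listed at 0, or within 0.01 FPKM of it, in both libraries of a group, so no fold is given. On simulated data of about 8569 tested genes, 200 of them changed, limma called on average 7 to 10 unchanged genes per run, most of them at 0 in both libraries of a group. These were 23.6%, 6.8% and 5.6% of the calls for changes of 4-fold, 8-fold and 16-fold. The shares rest on the 200 genes changed by design and do not carry over to the 7 real calls. With 7 to 10 unchanged genes called per run, all 7 real calls may be of unchanged genes. Fam177a (NCBI gene 73385; chromosome 12, 55124435 to 55142104) was listed at 0 in both controls and had 38.6 and 45.2 FPKM in the libraries labelled ERα-deficient (adjusted p = 0.0461 in limma). It shares 3863 bases at high identity with 1700047I17Rik2, and its assignment is uncertain. BC028528 (NCBI gene 229600; chromosome 3, 95883945 to 95892062) was listed at 0 in controls and had 38.3 and 34.4 FPKM (adjusted p = 0.0495 in limma), on only an estimated 8 and 7.9 fragments. Its exons overlap C920021L13Rik over 698 bases on the opposite strand. H2-Q9, a class I histocompatibility gene with close paralogs, had 74.4 and 124 FPKM in controls and at most 0.01 in the other group (adjusted p = 0.0279). The remaining 4, which fell, were the short RNAs Snord96a, Snord104, Mir3064 and Mir7674, at 38.9 to 245 FPKM in controls and listed at 0 in the other group. Without the 141 short RNAs tested, or without any single library, limma called 0 genes in either direction, with 2103 at an unadjusted p under 0.05 for the former and 1234 to 2042 for the latter. A pseudocount of 0.1, no filter, no trend or a replicate block also left 0 genes, with 1813, 2190, 1996 and 1888 at an unadjusted p under 0.05. Quantile scaling, median-ratio scaling, robust variances and scaling to T cell genes kept all 7, a mean FPKM of at least 5 kept 4, and with voom weights Fam177a was the 1 of them called (adjusted p = 0.0424).

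Genes of the T cell receptor and its signalling were lower as a group, except when the libraries were scaled to T cell genes, where their median log2 fold change was 1.15, below the 2.11 of all genes. Of 29 tested members of the TCR signalling list, 28 had a lower mean in the libraries labelled ERα-deficient and 25 did not overlap between groups, with a median log2 fold change of -1.35. Counts of genes that fell were 0 over all genes tested and 16 adjusted over the list alone. The list lay below other genes in camera (adjusted p = 1.31e-11), and with an estimated correlation the adjusted p was 0.623. In fry, which asks whether the genes of a list move 1 way, the smallest adjusted p over all lists was 0.0714, for this list among others, and none passed. Lat, the adaptor phosphorylated after receptor engagement, had 168 ± 44.4 FPKM in controls and 17.2 ± 0.25 in the other group (SD, n = 2; log2 fold change -3.19 ± 0.32, SE, adjusted p = 0.082 in limma). Lck, the kinase bound to CD4, had 158 ± 34.4 and 18.3 ± 1.36 FPKM (SD, n = 2). Cd3e had 62.9 ± 3.72 and 9.94 ± 0.18 FPKM. Cd4, a surface protein used for the sort, had 141 ± 18.9 and 52.5 ± 0.12 (SD, n = 2). Vav1, expressed in many blood cells, had 32.1 ± 0.08 and 32.5 ± 5.15 FPKM (SD, n = 2). With voom weights, 8 of 17 tested members fell and 0 rose. In the same libraries markers of macrophages were higher by a median of 3.64 on the log2 scale.

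None of the other genes chosen by smallest p among those lower without overlap passed in limma (adjusted p 0.082 for each). Cd40lg, the ligand by which helper T cells activate other cells, had 44.1 ± 6.53 and 3.06 ± 0.23 FPKM (SD, n = 2). The others were Ms4a4b (270 ± 45.6 and 21.8 ± 9.23), Cd96 (68.7 ± 16.1 and 7.24 ± 1.27), Gimap7 (87.1 ± 7.01 and 6.81 ± 3.66), Cd5 (69.8 ± 11.2 and 9.06 ± 1.9) and the histone gene Hist4h4 (21.0 and 25.7, and listed at 0 in both libraries labelled ERα-deficient). In the higher direction the same rule gave Lrrc25 (2.93 ± 0.93 and 38.1 ± 4.54 FPKM), Zfp119a (2.21 ± 1.39 and 43.6 ± 6.39), Tcof1 (24.2 ± 9.14 and 205 ± 35.0), Tmem51 (0 and 0.8, and 35.2 and 36.4), and Phospho1 (17.8 ± 6.05 and 186 ± 60.3). Ace, Fam213b and Smim22 were listed at 0 in both controls and had means of 18.1 ± 2.97, 19.6 ± 5.53 and 16.8 ± 1.27 FPKM (SD, n = 2) in the other group. Each of these 8 had an adjusted p of 0.082 in limma. The values of Fam213b in the libraries labelled ERα-deficient rest on an estimated 6.8 and 11.2 fragments. Phospho1 shares 1818 bases of exon with Zfp652, and Ace 295 bases with Gm11651 on the opposite strand, so their values are uncertain. Lrrc25 shares sequence with transcripts of 86 other genes, which leaves its value uncertain too. With voom weights, Ms4a4b (adjusted p = 0.00106), Cd3g and Lat (0.00968 each), Cd96 and Cd5 (0.0105 each) and Gimap7 (0.0301) fell, and Phospho1 (0.00674) and Lrrc25 (0.0457) rose.

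**Figure D1:**
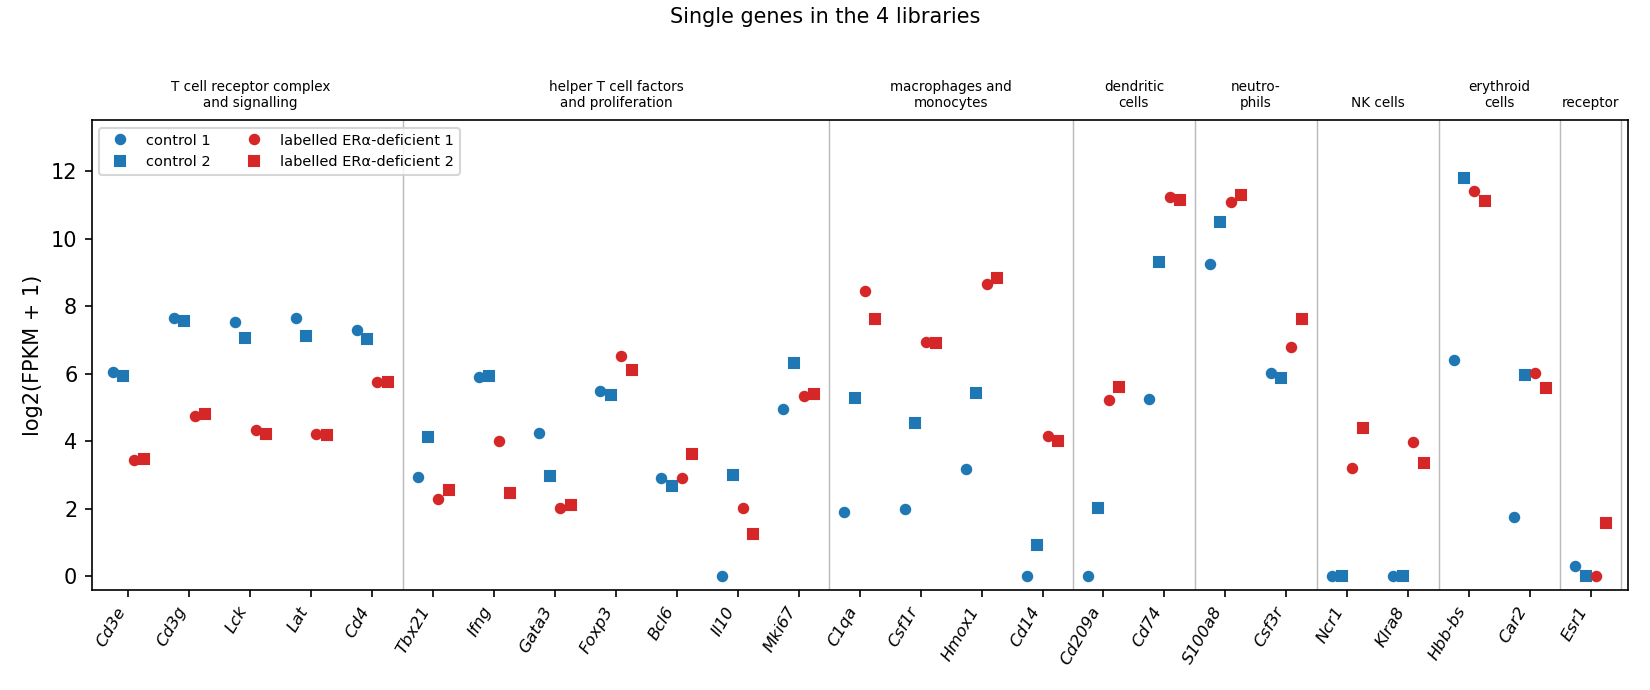
Expression of single genes, grouped by function or cell type along the horizontal axis, as log2(FPKM + 1) on the vertical axis, with 1 point per library (blue controls, red libraries labelled ERα-deficient, circles replicate 1, squares replicate 2). Cd3e lies at 65.5 and 60.2 FPKM in the controls and at 9.81 and 10.1 in the other libraries, C1qa at 2.7 and 38.2 against 349 and 194, and Hbb-bs at 83.3 in control 1 against at least 2227 in the other 3.

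Markers of macrophages and monocytes were higher in the libraries labelled ERα-deficient without exception. All 22 members had higher values in both of these libraries than in both controls, with a median log2 fold change of 3.64. Over all genes tested 0 rose, and 21 rose adjusted over the list alone. The list lay above other genes in camera (adjusted p = 1.18e-14), and the adjusted p was 0.623 with an estimated correlation and 0.18 in fry. C1qa, a complement component made by tissue macrophages, had 20.4 ± 25.1 FPKM in controls and 271 ± 110 in the other group (SD, n = 2). Csf1r, the receptor for the macrophage growth factor, had 12.6 ± 13.7 and 121 ± 0.61 FPKM (SD, n = 2), and Cd14 had 0 and 0.9 in controls against 16.7 and 15.0. The controls themselves differed: all 22 markers were higher in control 2 than in control 1, by a median of 2.46 on the log2 scale, and the mean over the list was 6.72 and 34.1 FPKM in the controls against 181 and 206. With voom weights, 13 of 17 tested markers rose and 0 fell. In these libraries T cell receptor signalling genes were lower by a median of 1.35 on the log2 scale, as given above.

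Other leukocyte markers were also higher, to differing degrees. The dendritic cell list had a median log2 fold change of 2.85 (camera adjusted p = 0.000487, and adjusted p = 0.623 with an estimated correlation), with 12 of 14 members higher on average. The controls differed here too: the list median of log2(FPKM + 1) was 1.3 in control 1 and 3.89 in control 2. In the libraries labelled ERα-deficient it was 5.4 and 5.51. Counts that rose were 0 over all genes and 2 adjusted over the list alone. Cd209a had 0 and 3.06 FPKM in controls and 36.6 and 47.5 in the other group, and Batf3 0 and 6.57 against 52.3 and 41.8. Cd74, the class II invariant chain, had 37.4 and 636 against 2406 and 2251. Leaving out the second library labelled ERα-deficient ended this list's call (adjusted p = 0.0842). NK cell and innate lymphocyte markers had a median of 2.83 (camera adjusted p = 3.63e-07, and adjusted p = 0.623 with an estimated correlation), with 11 of 12 members higher on average. Counts that rose were 0 over all genes and 9 adjusted over the list alone. Ncr1, an activating receptor of NK cells, and Klra8 were listed at 0 in both controls and had 8.25 and 19.8, and 14.7 and 9.28 FPKM, in the other group. Klra8 has near-identical relatives, with 1115 bases shared with Klra14-ps. Eomes, a member also made by T cells, had 30.2 ± 4.42 and 17.0 ± 0.74 FPKM (SD, n = 2). Neutrophil markers had a smaller median of 1.0 (camera adjusted p = 0.000487, and adjusted p = 0.623 with an estimated correlation), with 15 of 16 higher on average and 0 called over all genes or adjusted over the list alone. Csf3r, the receptor for granulocyte growth factor, had 60.8 ± 5.25 and 152 ± 59.1 FPKM (SD, n = 2), Ly6g had 0 and 1.67 against 6.65 and 5.97, and S100a8 had 607 and 1448 against 2176 and 2525. The Ly6g values rest on an estimated 0 and 1 fragments in controls and 3.1 and 3 in the libraries labelled ERα-deficient. Csf3r shares sequence with transcripts of 175 other genes, over up to 1518 bases, so its value is uncertain.

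Red cell transcripts set control 1 apart from the other 3 libraries. Hbb-bs, a β-globin gene, had 83.3 FPKM in control 1 and 3579 in control 2, against 2744 and 2227 in the libraries labelled ERα-deficient, and Car2 had 2.39 and 61.0 against 64.3 and 46.8. The erythroid list had a median log2 fold change of 1.68 with 12 of 13 members higher on average, 1 without overlap (Car1, 1.23 and 21.9 against 37.2 and 30.4 FPKM) and 0 called over all genes or adjusted over the list alone. Its camera call (adjusted p = 0.0458, and adjusted p = 0.76 with an estimated correlation) turned direction without control 1 (lower, adjusted p = 0.149) and was lost without the first or the second library labelled ERα-deficient (adjusted p = 0.411 and 0.16). Without control 2 the adjusted p was 3.22e-09. B cell, platelet, CD8 and stromal markers were mostly low or absent. The B and plasma cell list (5 tested, median 1.06, camera adjusted p = 0.37) and the platelet list (4 tested, median 0.19, camera adjusted p = 0.728) were not called, and neither had a member called over all genes or adjusted over the list alone. Cd22 had 58.8 ± 10.03 and 138 ± 86.7 FPKM, and Fcer2a 17.0 ± 0.66 and 6.12 ± 6.85 (SD, n = 2). Ppbp had 0 and 1.39 against 7.39 and 0, and Itgb3 5.12 ± 4.48 against 5.43 ± 1.09. Cd8a had 10.4 ± 3.12 and 20.1 ± 8.45 FPKM and Cd8b1 50.8 ± 21.7 and 89.4 ± 56.8, the latter sharing sequence with transcripts of 76 other genes. Of stroma and endothelium, Pecam1 had 14.7 ± 4.67 and 13.0 ± 3.71 FPKM and Ccl19 was above 0 in control 2 alone, at 4.33. Xist had 28.8 ± 4.99 and 28.5 ± 1.79 FPKM and Tsix, which overlaps it on the opposite strand, 252 ± 40.5 and 241 ± 18.6, while the Y-linked Ddx3y was at most 0.31 in any library.

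**Figure D2:**
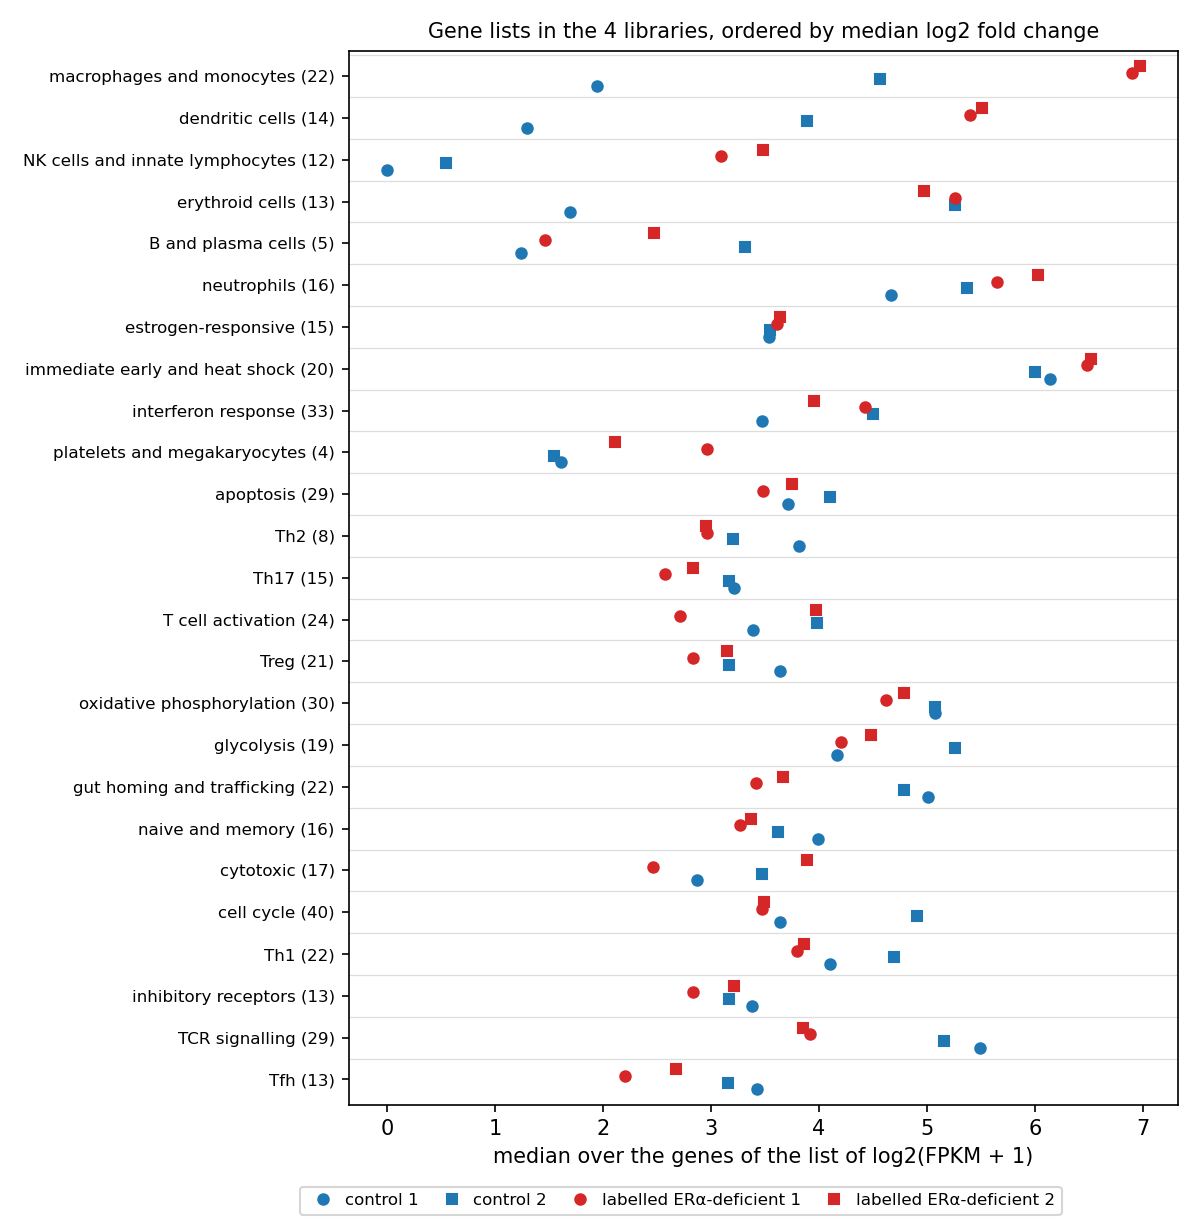
Median of log2(FPKM + 1) over the tested genes of each list (horizontal axis) for each library (blue controls, red libraries labelled ERα-deficient, circles replicate 1, squares replicate 2), with the number of genes in parentheses. The macrophage list lies at 1.94 and 4.56 in the controls and at 6.90 and 6.97 in the other libraries, and the TCR signalling list at 5.49 and 5.16 against 3.92 and 3.85.

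Among the helper T cell types, the Th1 and follicular helper lists were lower, and Foxp3 stood against the trend of T cell genes. Scaled to T cell genes, the medians of these lists were 1.51 and 0.73, below the 2.11 of all genes but above 0. By their medians both lists thus fell less than the 23 genes restricted to T cells, whose median was -2.54. Ifng, the signature cytokine of Th1 cells, had 59.7 ± 1.14 FPKM in controls and 9.78 ± 7.45 in the libraries labelled ERα-deficient (SD, n = 2; log2 fold change -2.69 ± 0.56, SE, adjusted p = 0.148 in limma), on an estimated 48.7, 47.6, 9 and 3 fragments. Without the first or the second library labelled ERα-deficient its log2 fold change was -3.46 or -1.92. Tbx21, which encodes the Th1 factor T-bet, had 11.6 ± 6.89 and 4.40 ± 0.71 FPKM (log2 fold change -1.11 ± 0.53, SE, adjusted p = 0.383 in limma). Scaled to T cell genes its log2 fold change was 1.10, below the 2.11 of all genes but above 0, so it fell less than those T cell genes. With single libraries left out in turn, the log2 fold change of Tbx21 ranged from -1.70 to -0.52. Of 22 Th1 genes, 16 were lower on average, with a median of -0.87, 0 called over all genes, and 5 that fell and 1 that rose adjusted over the list alone. Its camera call (adjusted p = 0.0117, and adjusted p = 0.623 with an estimated correlation) was lost without control 2 (adjusted p = 0.266) and without the second library labelled ERα-deficient (0.077). The member higher was Hlx (1.02 ± 0.52 and 11.7 ± 0.95 FPKM), and Cxcr3, a chemokine receptor, had 20.7 ± 5.25 and 3.55 ± 0.27. Of 13 follicular helper genes, 11 were lower on average with a median of -1.67 (camera adjusted p = 0.000308, and adjusted p = 0.623 with an estimated correlation), 0 called over all genes, and 8 that fell and 1 that rose adjusted over the list alone. The call was lost at a mean FPKM of at least 5 (adjusted p = 0.0601) and with voom weights (0.12). Icos, a costimulatory receptor, had 18.3 ± 1.9 and 2.82 ± 1.41 FPKM, while Il6ra, also made by myeloid cells, had 6.73 ± 1.75 and 28.2 ± 3.3. Bcl6, the follicular helper factor, had 5.91 ± 0.74 and 8.90 ± 3.32 (SD, n = 2; log2 fold change 0.48 ± 0.45, SE, adjusted p = 0.628). The macrophage list moved in the opposite direction to these lists, with a median of 3.64.

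Foxp3, the regulatory T cell factor (NCBI gene 20371; chromosome X, 7579676 to 7595243), had 42.2 ± 2.48 FPKM in controls and 79.4 ± 16.8 in the libraries labelled ERα-deficient (SD, n = 2), a log2 fold change of 0.88 ± 0.31 (SE) that did not pass (adjusted p = 0.264 in limma). Its exons overlap 4 other annotated genes, among them Ccdc22 and Flicr. The regulatory T cell list as a whole was not called (21 tested, median -0.27, camera adjusted p = 0.221), with 0 called over all genes, and 4 that fell and 1 that rose adjusted over the list alone. Ctla4, an inhibitory receptor abundant in regulatory T cells, had 15.3 and 11.7 FPKM in controls and was listed at 0 in both libraries labelled ERα-deficient (adjusted p = 0.0929), and Il2rb had 29.8 ± 5.48 and 7.94 ± 0.87. The 15 tested Th17 genes had a median of -0.19 (2.01 when scaled to T cell genes, camera adjusted p = 0.503), with 0 called over all genes, and 1 that fell and 1 that rose adjusted over the list alone. Batf had 74.3 ± 15.5 and 10.97 ± 6.89 FPKM. Gata3, the Th2 factor, had 12.4 ± 7.82 and 3.16 ± 0.16 FPKM (log2 fold change -1.55 ± 0.55, SE, adjusted p = 0.272 in limma), and Ccr4 10.2 ± 0.97 and 5.38 ± 0.84. Scaled to T cell genes the log2 fold change of Gata3 was 0.65, below the 2.11 of all genes but above 0. With single libraries left out in turn, the log2 fold change of Gata3 ranged from -2.19 to -0.92. The 8 tested Th2 genes had a median of -0.05 (0.02 with median-ratio scaling, camera adjusted p = 0.692) with 0 called over all genes or adjusted over the list alone. Il10 had 0 and 6.99 FPKM in controls against 3.09 and 1.39, on at most 6 estimated fragments, and its difference was not detectable at this depth.

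Proliferation genes were lower as a group, a call that needed control 2. Scaled to T cell genes their median was 1.68, where that of all genes was 2.11. By this median they fell less than the genes restricted to T cells. Mki67, a marker of dividing cells, had 29.7 and 78.0 FPKM in controls and 39.8 and 41.2 in the libraries labelled ERα-deficient (log2 fold change -0.25 ± 0.50, SE, adjusted p = 0.838 in limma, turning to 0.43 without control 2 and 2.27 when scaled to T cell genes). Top2a had 15.2 and 49.1 against 3.79 and 7.82 FPKM, and Ccnb1 4.33 and 17.5 against 0 and 2.32. Of 40 cell cycle genes, 33 were lower on average with a median of -0.66, with 0 called over all genes or adjusted over the list alone. The camera call (adjusted p = 0.00936, and adjusted p = 0.76 with an estimated correlation) was lost without control 2 (0.898) or without the second library labelled ERα-deficient (0.208), and without control 1 the adjusted p was 3.11e-08. Erythroid precursors also divide, and their markers were higher in control 2 than in control 1. The erythroid list median of log2(FPKM + 1) was 1.69 and 5.26 in the controls, and 5.26 and 4.97 in the libraries labelled ERα-deficient. The cell cycle median was 3.64 and 4.91 in the controls, against 3.47 and 3.49. These medians argue against erythroid RNA as the sole source of the higher cell cycle values of control 2.

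The other T cell lists were not called by camera, and none of their members was called over all genes in the main test. With voom weights, 2 of 9 tested cytotoxic genes rose, Tyrobp and Fcer1g, which also stand in the NK cell list. Of 7 naive and memory genes 1 rose (Actn1). In that fit 1 of 17 gut homing and trafficking genes fell, and T cell activation and inhibitory receptors had 0 calls. Scaled to T cell genes the medians of these lists were 1.18 to 1.91, where that of all genes was 2.11. By these medians the lists fell less than the genes restricted to T cells. For T cell activation the median of 24 genes was -0.22 (adjusted p = 0.336), with 4 that fell and 1 that rose adjusted over the list alone, and Cd69, an early activation marker, had 34.1 ± 7.23 and 5.88 ± 0.45 FPKM (SD, n = 2). Naive and memory genes had a median of -0.64 (16 tested, adjusted p = 0.221, 3 that fell and 1 that rose over the list alone). Lef1 had 19.1 ± 10.1 and 1.5 ± 0.53 FPKM and S1pr1, the receptor for exit from lymphoid organs, 21.7 ± 13.3 and 1.87 ± 0.14. The cytotoxic list had a median of -0.66 and a mean of 0.05 over 17 genes, with camera pointing lower (adjusted p = 0.558), and 2 that fell and 1 that rose adjusted over the list alone. It held members that went apart, such as Ctsw (63.8 ± 2.22 and 17.4 ± 5.07 FPKM) and Tyrobp, an adaptor of myeloid and NK cells (12.8 and 75.4 against 371 and 327), and 4 of its genes also stand in the NK cell list. Inhibitory receptors had a median of -1.22 (13 tested, adjusted p = 0.205, 3 that fell and 1 that rose over the list alone), with Cd244, also found on NK and myeloid cells, at 1.38 ± 1.41 and 16.4 ± 1.58 FPKM. Gut homing and trafficking genes had a median of -0.46 (22 tested, adjusted p = 0.128, 6 that fell and 1 that rose over the list alone).

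Metabolic, stress and hormone-response lists were not called either, with 0 members called over all genes in the main test. With voom weights, 2 of 7 tested estrogen-responsive genes rose in limma, Ctsd (adjusted p = 0.0337) and Ccnd1 (0.0444). In that fit 1 of 18 immediate early and heat shock genes also rose (Zfp36, adjusted p = 0.0353), and 0 members of these lists fell. Glycolysis genes had a median of -0.38 (19 tested, adjusted p = 0.221), with Ldha at 116 ± 18.6 and 71.8 ± 4.22 FPKM and Hif1a at 19.9 ± 4.15 and 10.4 ± 1.11 (SD, n = 2). Oxidative phosphorylation genes had a median of -0.36 (30 tested, adjusted p = 0.221), with Atp5b at 139 ± 33.5 and 73.6 ± 25.8 and Atp5g1 at 21.0 ± 6.07 and 9.79 ± 0.74. Both lists were lower without control 1 (adjusted p = 0.025 and 0.0444), and with an estimated correlation over all libraries the adjusted p was 0.773 for each. Interferon response genes had a median of 0.27 (33 tested, adjusted p = 0.205). They were higher without control 2 (adjusted p = 0.00213) and with voom weights (0.0249), and pointed lower without control 1 (0.906), with an adjusted p of 0.773 for all libraries with an estimated correlation. Their members Oas1a and Oas2 had 3.12 ± 2.26 and 14.4 ± 0.35, and 2.86 ± 2.49 and 14.5 ± 0.27 FPKM, and Oas1a shares 1861 bases with Oas1g. Apoptosis genes had a median of 0.08 (29 tested, adjusted p = 0.763), with Bbc3, a pro-apoptotic gene, at 10.4 ± 8.09 and 34.1 ± 14.8 FPKM and Fasl at 9.65 and 7.18 against 0 and 3.81. None of these 4 lists had a member called adjusted over the list alone. Classical estrogen-responsive genes had a median of 0.37 (15 tested, adjusted p = 0.215), with 3 that rose and 1 that fell adjusted over the list alone, among them Igf1, a growth factor also made by macrophages (0.42 ± 0.31 and 12.0 ± 1.74 FPKM), and Cish, an inhibitor of cytokine signalling (13.4 ± 3.8 and 1 ± 0.4). Immediate early and heat shock genes had a median of 0.35 (20 tested, adjusted p = 0.0516), with 3 that rose adjusted over the list alone. Atf3 had 0.72 and 5.32 against 42.4 and 90.6 FPKM and Zfp36 67.7 ± 3.46 against 168 ± 18.9 (SD, n = 2), and the list was called higher in 5 of 12 alternatives. These were no filter (adjusted p = 0.0483), a mean FPKM of at least 5 (0.0444), median-ratio scaling (0.0418), leaving out control 1 (0.025) and voom weights (0.00578), within a range up to 0.273. With an estimated correlation the adjusted p was 0.623. In the same libraries the macrophage list was higher by 3.64 and TCR signalling genes had a median of -1.35.

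**Figure D3:**
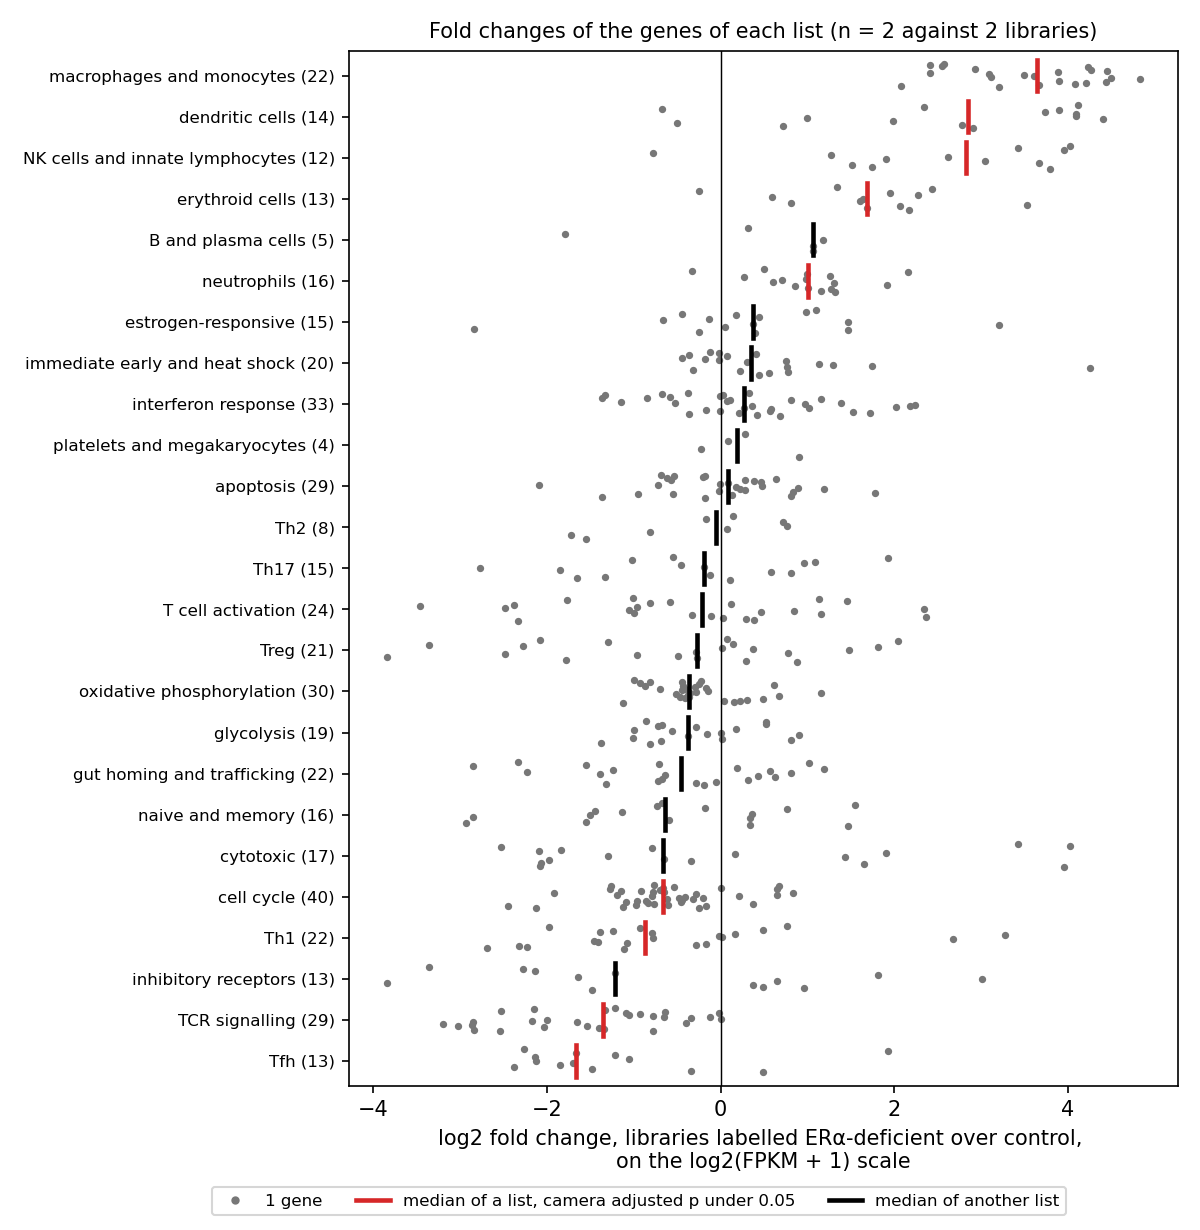
Log2 fold change of each tested gene (gray points) in each list, libraries labelled ERα-deficient over control on the log2(FPKM + 1) scale (horizontal axis, 2 against 2 libraries), without scaling to T cell genes (which shifts the median of all genes to 2.11), with the median as a bar, red where the camera adjusted p with the preset correlation is under 0.05. The bars run from -1.67 for follicular helper genes to 3.64 for macrophage markers, and the 9 red bars lose their call with an estimated correlation, where the lowest adjusted p is 0.623.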

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

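Voom weights, the removal of short RNAs and the scaling to T cell genes were chosen after the data were seen, and all other settings before. Against 2 higher and 5 lower genes, limma called 0 and 0 with a pseudocount of 0.1 (1813 at an unadjusted p under 0.05), no filter (2190), no trend (1996), a replicate block (1888) or short RNAs left out (2103), and 0 to 0 in each direction over the 4 fits that each left out 1 library (1234 to 2042), where the lone library of a group is assumed to vary like the others. A mean FPKM of at least 5 gave 0 higher and 4 lower, an adjusted p under 0.10 gave 18 and 32, voom weights 138 and 49, and scaling to T cell genes 9133 and 34; quantile and median-ratio scaling, robust variances and a log2 fold change of at least 1 in size left 2 and 5. The 9 list calls became 0 with an estimated correlation and 5 to 11 without 1 library, the 5 without the second library labelled ERα-deficient. The loss with an estimated correlation does not measure correlation alone. For Tfh the estimate was -0.02, below the preset 0.01, yet the unadjusted camera p went from 4.92e-05 to 0.0501. With an estimated correlation, camera uses only the few residual degrees of freedom of the libraries. Scaling to T cell genes moved the median log2 fold change of all genes from -0.07 to 2.11. TCR signalling stood at 1.15 and Tfh at 0.73 there, and by its construction this scaling hardly changes the order of the lists. TCR signalling, macrophage, neutrophil and NK cell lists were called in each of the 12 alternatives run with the preset correlation. The Th1 call was lost without control 2 (adjusted p = 0.266), without the second library labelled ERα-deficient (0.077) and with voom (0.0545, range 0.000789 to 0.266). The Tfh call was lost at a mean FPKM of at least 5 (0.0601) and with voom (0.12, range 0.000121 to 0.12), and the erythroid call also with a pseudocount of 0.1 (0.0674) and median-ratio scaling (0.0579, range 3.22e-09 to 0.411). Of 1093 values for 75 named genes, 983 kept direction and side of the threshold, 48 passed it newly, 30 no longer passed and 32 reversed. Scaling to T cell genes reversed Tbx21 (1.10), Gata3 (0.65), Mki67 (2.27), Cxcr3 (0.047), Ccr4 (1.45), Il2rb (0.64), Cd69 (0.064), Top2a (0.21), Ctsw (0.66), Ldha (1.88), Hif1a (1.54), Atp5g1 (1.40), Atp5b (1.62), Fcer2a (0.43), Pecam1 (2.24), Tsix (2.52) and Xist (2.48), by its own construction, since it shifts the median of all genes to 2.11; of these Mki67, Pecam1, Tsix and Xist lie above that shift. Median-ratio scaling reversed Tsix (0.015) and Xist (0.066). Leaving out 1 library gave ranges that cross 0 for Il10 (-1.35 to 1.65), Mki67 (-0.93 to 0.43), Car2 (-0.15 to 4.04), Ppbp (-0.63 to 2.44), Itgb3 (-0.54 to 1.11), Pecam1 (-0.47 to 0.15), Tsix (-0.22 to 0.10) and Xist (-0.18 to 0.17), and from -2.41 to 0 for Ccl19. Apart from that scaling and the smaller number of libraries, the cause was not tested. Planned tests on whole fragment counts were not run, because fragments were recovered only in part. Depth limits values of a few FPKM, where 3 fragments on 2000 bases amount to 2.16 to 3.0.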

Other observations

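All tests in this part were chosen after the results were seen. Genes of red pulp macrophages, which clear aged red cells in the spleen, had a median log2 fold change of 4.04 in the libraries labelled ERα-deficient. This list of 12 was written after the macrophage values were seen and 6 of its genes also stand in the macrophage list, so it describes that pattern further and does not test it. The 23 genes restricted to T cells, also listed afterwards, had a median of -2.54 and a range from -3.19 to -0.78, and 11 of them also stand in the TCR signalling list. With voom weights in limma, 6 of 8 tested red pulp macrophage genes rose and 10 of 13 tested T cell genes fell. Among 618 gene ontology terms, 7 were higher and 0 lower in camera, led by phagocytosis (17 genes, median 2.79, adjusted p = 5.53e-07), regulation of angiogenesis (33 genes, median 1.10, adjusted p = 0.000664) and positive regulation of endocytosis (25 genes, median 1.85, adjusted p = 0.00857). The others were defense response (0.035), fat cell differentiation (0.0397), response to molecule of bacterial origin (0.0397) and cellular metabolic process (0.0438). With an estimated correlation 0 terms passed, and these had an adjusted p of 0.975. The 3 splits of the 4 libraries are too few for a share under 0.05: the real one had 7 genes at an adjusted p under 0.05 and 2050 at an unadjusted p under 0.05, and the highest other 0 and 206 in limma, where mixing the groups widens the spread within them.

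The first pattern is lower T cell transcripts with higher macrophage transcripts in the libraries labelled ERα-deficient. The list medians argue against a smaller T cell share with all other cell types raised alike. That of macrophages, 3.64, exceeds that of neutrophils, 1.0, by 2.64. The permutation p was 2e-05 (two-sided), the smallest that 100000 resamples can give. Both medians were known when this test was chosen, so it adds no support of its own. Its p measures the spread over genes that are not independent, not the spread between libraries. More macrophage RNA in these sorted samples stays open as a hypothesis. A sort for CD3 and CD4 is meant to remove other cells, but transcripts typical of them were present. The erythroid list had means of 17 and 646 FPKM in the controls and 515 and 403 in the other group. The aim of the sort therefore does not argue against this hypothesis. That 100% of the 22 markers were higher in both of these libraries than in both controls restates the pattern and decides nothing. C1qa, for one, stood at 349 and 194 FPKM and Cd74 at 2406 and 2251. The genotype of the T cells cannot be told apart from more macrophage RNA, since genotype follows the groups. Control 2 exceeded control 1 by a median of 2.46 over the same markers, beside 2.38 between the libraries labelled ERα-deficient and control 2. A difference between mice, sorts or preparation days may also follow the groups and was not tested.

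The second pattern is the higher value of Foxp3, which did not pass the test, against lower values of T cell genes. Ccdc22 shares 590 bases with a Foxp3 transcript of 3834 bases. At its listed level, at most 3.51 FPKM in the libraries labelled ERα-deficient, it would add up to 0.54 FPKM there, against a difference of 37.2. A first version over all 4 libraries gave up to 4.36 FPKM, from control 1, where Ccdc22 was listed at 28.35 FPKM. That value was not small enough to meet the bound set for it. Ccdc22 was thus listed lower in the libraries where Foxp3 was higher than in control 1. The test was then narrowed to the libraries where Foxp3 was higher. Fragments of Ccdc22 that were assigned to Foxp3 would be missing from the listed level of Ccdc22, so neither version excludes this overlap. A larger share of regulatory T cells stays open. All 6 tested genes of 9 restricted to these cells were below 0 (exact sign test p = 0.031, two-sided, median -1.73). The 23 genes restricted to T cells had a median of -2.54, so a test against 0 cannot separate the regulatory share from that shift. The list was also written when Ctla4 had been seen and gives an exact sign test p of 0.0625 without it. The regulatory T cell list fixed beforehand held 10 higher and 11 lower genes. Flicr, which overlaps Foxp3 over 853 bases on the same strand, was not analysed here and may add to its values, and the genotype stays open and untested.

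The third pattern is that genes not typical of T cells hold some of the highest values in all 4 libraries, such as Cnbd2 (mean 8412 FPKM), Omd, a gene of bone and connective tissue (5620), and Nanog, a stem cell factor (1043). Among the 50 highest genes, 36.0% overlap exons of another gene, beside 38.8% of 500 genes drawn at 5 to 50 FPKM (Fisher's exact p = 0.762), and 32.0% share sequence with at least 10 other genes, beside 11.2% (p = 0.000203). Sequence shared with any other gene was found for 78.0%, beside 50.8% (Fisher's exact p = 0.000283). These shares cover all 50 genes and not the untypical ones alone, and 6 of the 16 genes with much repeated sequence are ribosomal or elongation factor genes, so they decide neither explanation. Single genes differ: Omd shares sequence with 144 genes and Snx22 (1521) 825 bases of exon with Ppib, while Zmynd8 (3114) had none on its longest transcript, though other transcripts of it share 204 bases with Mrpl13, and no biological explanation was tested.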
